A study of Homo sapiens with 54 samples.

How the data were processed

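Primary human hepatocytes from 3 donors were kept in micropatterned coculture with mouse fibroblasts as feeder cells and exposed to tolvaptan or to its DMSO vehicle. Tolvaptan is an antagonist of the vasopressin V2 receptor. It was given at 0.01, 0.1, 1, 20 and 50 µM, and cells were collected after 4, 24 and 72 h. RNA of 8 wells was pooled for each array, and 54 Affymetrix arrays cover each donor, time and treatment once, which makes 18 groups of 3 arrays. Groups, times, concentrations and donor numbers were taken from the sample labels. Per the labels, RNA of the mouse feeder cells was present with the human RNA on each chip, so a probe can also read mouse transcripts. Some protocol passages in the labels describe mice and another compound and were disregarded.

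The deposited values are on the log2 scale and were made by the authors with RMA, a background correction, normalization and probe summary method, in Partek 6.6, per the submitters' processing notes. The deposited table holds 20216 probe sets, and how these were chosen is not given in the sources used here. Array medians ran from 4.949 to 5.587. As RMA normalizes before the probe summary, these medians do not show on which probe sets a quantile step was made. The arrays carry no read depth, and the precision is limited by their number. No detection call was used. No slide or scan date was given, so batches other than donor and time could not be examined.

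The platform's annotation paired 18986 probe sets with 1 gene symbol, 72 with several and 1158 with none. Symbols were updated through the Entrez number for 18974 probe sets with the RefSeq table of assembly GRCh38.p14, and 12 kept the older symbol. No genome build is named for the values, so no coordinates are given. For each gene the probe set with the highest mean over the arrays was used, which left 11154 genes, 4907 of them with more than 1 probe set. The probe sets of sex chromosome markers were left out because the donors are people. Among 224 pairs of a named gene and a contrast with several probe sets, all probe sets moved in one direction in 198. A probe set was called in the opposite direction in 4 pairs, which are ACACA and FN1 at 50 µM and 24 h, UGT1A6 at 50 µM and 72 h and ME1 at 20 µM and 72 h.

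Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, in a fit of all 54 arrays with the 18 groups and 9 blocks, 1 for each donor at each time, because each donor at each time forms a complete set of treatments. The fit had 30 residual degrees of freedom and a prior of 5.19. Vehicle over time was fitted with a block per donor. P-values were adjusted by Benjamini-Hochberg over the genes of each contrast, and a gene was called at an adjusted p under 0.05. The pairing was checked on deviations from group means: arrays of the same donor and time correlated at 0.28 to 0.86 in 135 of 135 pairs. Arrays of different donors at the same time correlated at -0.78 to 0.06 over 324 pairs. Taking deviations from means of 3 arrays pushes the latter below 0 by arithmetic, so only the first range bears on the pairing. The highest correlation between 2 arrays over all genes was 0.9965, between arrays of different groups. An error given as ± is the standard error of the log2 fold change unless it is called SD, and n is 3 donors in every group. With the blocks fitted, p-values measure how much the differences between groups vary across these 3 donors, not the spread of donor levels. That spread was estimated over all 54 arrays and all times, not from the groups compared alone.

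Gene lists were fixed before the data were examined, 50 in all. The 48 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 for 20 and 50 µM against vehicle at the 3 times, with adjustment over the 288 tests. The test was repeated with the correlation estimated from the residuals and with fry. camera compares a list with the other genes. The named genes follow a rule set before the data were examined. For each contrast of 20 or 50 µM with vehicle these are the 6 largest rises and 6 largest falls among called genes that moved the same way in 3 donors, and up to 4 called members of each list with the largest change at 50 µM, or the 2 members with the highest level where none was called. For the other contrasts they are the 3 largest called changes each way. Immunoglobulin and HLA genes, genes commonly deleted in some people and reading frames known only by a LOC number were not named under the rule.

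On simulated arrays with the real spreads, in which 200 of 11154 genes were changed for 50 µM against vehicle at 72 h, the fit recovered 60 percent of genes changed 1.5-fold, 98 percent of those changed 2-fold and 100 percent of those changed 4-fold or 8-fold, 50 genes each. It called 6 unchanged genes among 185 calls. The simulated noise was drawn independently for each gene and array, with no shift of a whole array and no correlation between genes. These rates therefore do not describe errors that such structure makes in the real arrays. The alternatives were the fit without the donor block, 1 block per donor across times, fits on the arrays of the times or of the groups compared, all probe sets, the mean of a gene's probe sets, the genes above the median level, centring on housekeeping genes or on secreted hepatocyte proteins, a repeated quantile normalization, array weights, a variance trend with a robust prior, and leaving out each donor. After the array medians were seen, fits without the 24 h vehicle array of donor 1, and without the 3 arrays with the lowest medians at 24 h, were added.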

Results

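The expression of 11154 genes was measured on 54 arrays of cultured human hepatocytes, 3 donors in each of 18 groups, to describe how tolvaptan at 0.01 to 50 µM altered transcription after 4, 24 and 72 h. Values are log2 RMA signals as the authors deposited them, and differences are log2 fold changes against the vehicle of the same time, fitted with the donor as a block. The 24 h vehicle array of donor 1 stood apart most. It had the lowest median of the 54 arrays, 4.949, and lay 0.40 below the mean of the same donor's 3 arrays at 1 µM and below (median difference -0.4 over all genes), with 86 percent of genes lower. The same difference was 0.02 and 0.08 for the 24 h vehicle arrays of the other donors. The 20 µM array of the same donor and time had the next lowest median, 5.168, and the widest interquartile range, 3.387, and it enters every 20 µM result at 24 h. Counts of calls over all genes at 24 h, and of called members of the lists, are therefore given with and without the vehicle array, and at 20 µM also without the 3 arrays at 24 h with the lowest medians, which include both.

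Concentrations of 1 µM and below gave almost no calls. Over the 9 contrasts with vehicle, 2 genes were called, both at 24 h: CACUL1 at 0.1 µM, 0.79 ± 0.14 (adjusted p = 0.0438), and USP31 at 1 µM, 0.98 ± 0.16 (adjusted p = 0.00398), each higher in 3 of 3 donors. By limma's unadjusted p, between 166 and 455 genes passed at 4 and 72 h and between 1862 and 2045 at 24 h, where the low vehicle array enters every contrast. Without that array neither passed (0.71 with adjusted p = 0.278, and 0.83 with adjusted p = 0.113) and 1 gene was called. Without donor 1, 2 or 3 the number was 4, 837 and 0. The low array has a larger share of the 24 h vehicle without donor 2, as also without donor 3. What raised the number to 837 was not tested. Other settings gave between 0 and 556. At 24 h the median difference of all genes was 0.118, 0.094 and 0.119 at 0.01, 0.1 and 1 µM.

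The untreated cultures themselves changed with time. From 4 to 72 h in vehicle, TNFSF10, which encodes the death ligand TRAIL, rose by 3.27 ± 0.39, DEPP1 by 2.80 ± 0.24 and PLXNC1 by 2.50 ± 0.29. SLC13A5, the citrate transporter of the hepatocyte membrane, fell by 3.17 ± 0.33, the lectin gene MBL2 fell by 3.02 ± 0.46 and the mannose receptor gene MRC1 fell by 2.71 ± 0.41. By 24 h TNFSF10 had risen by 2.77 ± 0.39, PDK4 by 2.66 ± 0.61 and MRAP by 2.37 ± 0.20, and SLC13A5 had fallen by 2.66 ± 0.33, KLHL29 by 2.47 ± 0.50 and DIP2C-AS1 by 2.43 ± 0.28. At 72 h 1734 genes were higher and 741 lower than at 4 h (adjusted p under 0.05), with 1317 and 1301 after a repeated quantile normalization. At 24 h 452 were higher and 899 lower, but 1687 higher and 532 lower without the low vehicle array, so the balance at 24 h rests on that array. It was also 953 higher and 517 lower after housekeeping centring, 638 and 320 after centring on secreted proteins, and 927 and 846 after quantile normalization. A fit without the donor block called 447 and 1046 genes at 24 and 72 h.

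At 4 h few genes responded to 50 µM. Of 28 members of the ATF4 integrated stress response list, 11 rose and none fell (17 rose, adjusted over the list alone), with a median change of 0.36 (camera adjusted p = 3.65e-25, and adjusted p = 0.0185 with an estimated correlation). The secreted stress cytokine gene GDF15 rose by 1.80 ± 0.27, the transcription factor genes ATF3 and DDIT3 by 1.52 ± 0.27 and 1.51 ± 0.29, and the cystine transporter gene SLC7A11 by 1.47 ± 0.28. DDIT3 was higher in 2 of 3 donors and the other 3 genes in 3 of 3. These sizes rest in part on donor 3, without whom they were 1.17, 0.82, 0.80 and 0.90 in the order given and none passed. IGFBP1, which encodes a binding protein of insulin-like growth factors, rose by 2.33 ± 0.42, higher in 2 of 3 donors, and was at 1.34 without donor 3 (adjusted p = 0.959) and 3.50 without donor 1. The heme oxygenase gene HMOX1 rose by 1.53 ± 0.28, C11orf96 by 1.55 ± 0.27, RBM24 by 1.49 ± 0.28 and MYC, 1 of 22 immediate early genes called, by 1.09 ± 0.19 (C11orf96 0.77 and MYC 0.61 without donor 3). The chemokine gene CXCL2 fell by 1.23 ± 0.27, UTS2R by 0.51 ± 0.12, ZNF207 by 0.49 ± 0.10 and TARDBP by 0.36 ± 0.09. The immediate early list was called higher (median 0.3, camera adjusted p = 2.04e-08), but not with an estimated correlation (adjusted p = 0.162).

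In all 54 genes were called at 50 µM and 4 h, 49 higher and 5 lower. The count was 1 without the donor block, 0 when only the 4 h arrays were fitted, and between 0 and 246 when a donor was left out. At 20 µM no gene was called by limma at 4 h, with 360 genes at an unadjusted p under 0.05 and 5 genes called without donor 1, and no list held with an estimated correlation.

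At 20 µM the later times were marked by genes of drug metabolism. Of 12 targets of the xenobiotic receptors PXR and CAR, 11 rose at 24 h and 8 at 72 h, with medians of 1.18 and 1.21 and none falling (adjusted over the list alone 11 and 12). With the low vehicle array left out 10 rose at 24 h, with a median of 0.84, and without the 3 low arrays 7 rose, with a median of 0.78. The calls held with an estimated correlation, with adjusted p = 0.0167 at 24 h and adjusted p = 0.00402 at 72 h. ALAS1, the rate-limiting enzyme of heme synthesis, rose by 2.11 ± 0.20 at 24 h and 1.80 ± 0.20 at 72 h. The cytochrome P450 gene CYP3A4 rose by 1.47 ± 0.31 at 24 h, but was at 1.00 (adjusted p = 0.0721) without the low vehicle array and at 0.81 without donor 1. The drug efflux pump gene ABCB1 rose by 1.33 ± 0.16 at 24 h, and CYP2B6 and CYP2C8 rose by 2.11 ± 0.25 and 1.80 ± 0.20 at 72 h. CYP3A7, CYP3A43 and CYP2B7P, at 1.52 ± 0.24 (24 h), 1.82 ± 0.26 (72 h) and 1.82 ± 0.16 (72 h), resemble CYP3A4 or CYP2B6 in sequence, so their probes are not certain to be separate measurements. Of 7 targets of the dioxin receptor AHR, 2 rose at 72 h (4 adjusted over the list alone, adjusted p = 0.0455 with an estimated correlation), CYP1A1 by 1.48 ± 0.40 and UGT1A6 by 0.45 ± 0.08. The other of the 2 UGT1A6 probe sets had the opposite sign there and was not called.

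Inflammatory genes fell at 20 µM. Of 15 members of the NF-kB and cytokine list, 5 fell at 24 h and 3 at 72 h (10 at each time adjusted over the list alone), with medians of -0.63 and -0.45 and adjusted p = 0.0167 and 0.0272 with an estimated correlation. With that array left out 6 fell at 24 h (median -0.60), and without the 3 low arrays 4 fell (median -0.55). The neutrophil chemokine gene CXCL8 fell by 1.15 ± 0.19 and CXCL2 by 1.23 ± 0.27 at 24 h, and CCL20 fell by 1.29 ± 0.24 at 72 h. At 24 h the other of the 2 CXCL8 probe sets had the opposite sign and was not called. The interferon-induced chemokine gene CXCL10 fell by 1.43 ± 0.41 at 24 h and 1.85 ± 0.41 at 72 h, and was at -1.59 at 24 h without that array (adjusted p = 0.0577). At 24 h 12 of 22 NRF2 antioxidant genes rose and none fell (median 0.48, adjusted p = 0.0417 with an estimated correlation), and 16 adjusted over the list alone, among them HMOX1 by 1.05 ± 0.28 and TXNRD1 by 0.78 ± 0.12. Leaving out the low vehicle array, 7 rose (median 0.34), as without the 3 low arrays (median 0.39), and HMOX1 no longer passed (0.82, adjusted p = 0.131). The bile salt transporter gene SLC51B rose by 1.63 ± 0.29, SEC14L4 by 1.68 ± 0.17 and the clock gene NR1D2 by 1.57 ± 0.35, the last at 0.83 without that array (adjusted p = 0.116).

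At 72 h and 20 µM, 9 of 20 genes of the cytoskeleton and SRF target list fell and none rose (13 adjusted over the list alone, median -0.33, adjusted p = 0.0181 with an estimated correlation). TUBA1A, an alpha tubulin gene, fell by 1.60 ± 0.26 and the tropomyosin gene TPM1 by 0.48 ± 0.12. Of 20 fibroblast markers, expected from feeder cells, 1 fell in the same samples (median -0.11, camera adjusted p = 0.0302, adjusted p = 0.468 with an estimated correlation and 0.101 without the donor block). The cholangiocyte and progenitor markers were also lower, with a median of -0.28 over 10 genes (camera adjusted p = 0.0186, adjusted p = 0.395 with an estimated correlation and 0.125 without the donor block). None of those 10 was called over all genes, and 4 fell adjusted over the list alone. SLC13A5 rose by 2.19 ± 0.20, the gluconeogenic gene PCK1 by 1.95 ± 0.54 (1.39 without donor 2, adjusted p = 0.266) and AKR1D1, a bile acid synthesis enzyme, by 1.83 ± 0.19. LECT2 fell by 1.64 ± 0.16, APOBEC3B by 1.73 ± 0.35, RRAD by 1.72 ± 0.29 and the sterol exporter gene ABCG1 by 1.40 ± 0.24 (-0.91 without donor 2, adjusted p = 0.132). 

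At 20 µM, 564 genes were called higher and 157 lower at 24 h, and 202 higher and 223 lower at 72 h. Without the low vehicle array the 24 h numbers were 91 and 297, of which 88 higher and 80 lower calls were shared, and the 72 h numbers were 404 and 464. The low 20 µM array stays in that fit, where the median of all genes was -0.089. Without the 3 low arrays the 24 h numbers were 69 and 76, and without donor 1 they were 60 and 55, so the balance at 24 h is not settled. At 24 h they were 490 and 258 after housekeeping centring, 218 and 136 after centring on secreted proteins, and 454 and 423 after quantile normalization. At 72 h housekeeping centring gave 470 and 149 and centring on secreted proteins 265 and 112. The 72 h numbers were 165 and 217 without donor 1, 40 and 16 without donor 2, and 51 and 38 without donor 3. With no donor block 33 genes were called at 24 h and 15 at 72 h.

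Stress and detoxification lists were higher at 50 µM and 24 h. Of 28 ATF4 list members 20 rose (median 0.73), GDF15 by 2.45 ± 0.27, the amino acid transporter gene SLC3A2 by 1.68 ± 0.17 and ATF3 by 1.52 ± 0.27. Of 22 NRF2 genes 18 rose (median 0.72), HMOX1 by 1.95 ± 0.28, the sulfiredoxin gene SRXN1 by 1.80 ± 0.10 and the thioredoxin reductase gene TXNRD1 by 1.57 ± 0.12. All 8 measured metallothionein and zinc response genes rose, MT1M by 1.08 ± 0.14, and 17 of 20 ribosome biogenesis genes, RRS1 by 0.98 ± 0.12. Of 19 cholesterol synthesis genes 11 rose, including the epoxidase gene SQLE by 1.22 ± 0.11. The transcription factor gene MAFF rose by 2.53 ± 0.40 (1.63 without donor 1), ERN1, the endoplasmic reticulum stress sensor IRE1, by 2.16 ± 0.22, LINC01003 by 2.06 ± 0.22, ALAS1 by 2.04 ± 0.20 and MAP2 by 1.96 ± 0.26. None of these lists passed with an estimated correlation (adjusted p = 0.404, 0.0719, 0.241, 0.29 and 0.626 in the order given). Adjusted over the list alone, 22, 18, 8, 17 and 11 members rose. Without the low vehicle array 16, 13, 5, 10 and 8 members rose, 2 of the ATF4 list and 1 of the NRF2 list fell, and the medians were 0.61, 0.51, 0.48, 0.39 and 0.25. Each list was called by camera without it too.

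Genes of hepatocyte metabolism fell at 50 µM and 24 h. Of 17 amino acid and urea genes 14 fell and none rose, with a median of -0.63. PRODH, of proline breakdown, fell by 1.82 ± 0.16, GNMT by 1.22 ± 0.27 and TAT by 1.06 ± 0.19. Of 9 gluconeogenesis genes 6 fell and 1 rose. PCK1, the enzyme that commits the pathway, fell by 3.53 ± 0.54 and G6PC1 by 1.70 ± 0.29. Of 9 bile acid synthesis genes 6 fell, and CYP7A1, the rate-limiting enzyme, fell by 2.69 ± 0.44 and ACOX2 fell by 0.90 ± 0.10. Of 22 PPARA and fatty acid oxidation genes 12 fell and 1 rose, PDK4 falling by 2.06 ± 0.33 and CYP4A11 by 1.40 ± 0.32. Of 19 bile acid and drug transporters 9 fell and 5 rose, ABCB4, which exports phospholipid into bile, falling by 1.98 ± 0.20. Of 23 other drug metabolism genes 13 fell and 1 rose, ADH4 falling by 1.87 ± 0.14. Of 27 secreted hepatocyte proteins 10 fell by smaller amounts, with a median of -0.17. Only 9 of the 27 had a mean level under 11, and whether signals near the upper limit of the arrays understate falls was not tested. SLC1A2 fell by 2.88 ± 0.31, MRAP by 2.50 ± 0.16, KMO fell by 2.47 ± 0.23, IGF1 fell by 2.30 ± 0.22 and SREBF1, the lipogenic transcription factor, by 2.02 ± 0.21. With an estimated correlation none of these lists passed (adjusted p = 0.0719, 0.162, 0.469, 0.215, 0.404, 0.282 and 0.176 in the order given). Without the low vehicle array 15, 7, 6, 15, 11, 16 and 14 members fell, and the medians were -0.76, -0.69, -0.48, -0.51, -0.55, -0.41 and -0.22. Adjusted over the list alone, 15, 6, 6, 12, 9, 13 and 11 members fell. In the same samples 3 of 20 fibroblast markers fell and 1 rose (median -0.16, camera adjusted p = 0.0163, adjusted p = 0.404 with an estimated correlation). Without that array 7 of them fell and 1 rose, and the list was not called (median -0.11, adjusted p = 0.0549). PXR and CAR targets moved both ways, with 8 of 12 higher and 2 lower (median 0.65). That list missed the threshold (camera adjusted p = 0.056). When that array was left out 6 were higher and 2 lower, with a median of 0.43 and adjusted p = 0.0483.

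At 50 µM and 24 h 3476 genes were called, 2660 higher and 816 lower, and the median difference of all genes was 0.117. Without the low vehicle array 1256 were higher and 1531 lower, 1233 higher and 747 lower calls being shared, and the median difference was 0.01. With a repeated quantile normalization 1886 were higher and 1739 lower, and with centring on secreted proteins 4488 and 471, where the median of all genes moved to 0.266. Quantile normalization tends to even such splits by its method. Centring on secreted proteins, which fell themselves, raises the other genes, so neither setting decides the direction. The balance turned without the low vehicle array, so the excess of rises rests on that array. Rises were 40.5 percent of calls without donor 1, and 82.3 and 85.7 percent without donors 2 and 3. Which direction prevails apart from that array is not settled. Without the donor block 1190 genes were called, and with only the arrays of the 2 groups fitted 44. In that fit, and with only the arrays of the time fitted, 72 h had more calls than 24 h, at 284 against 44 and 2054 against 1726. In the plot of calls by concentration and time the balance at 24 h turned when the array was left out.

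**Figure D1:**
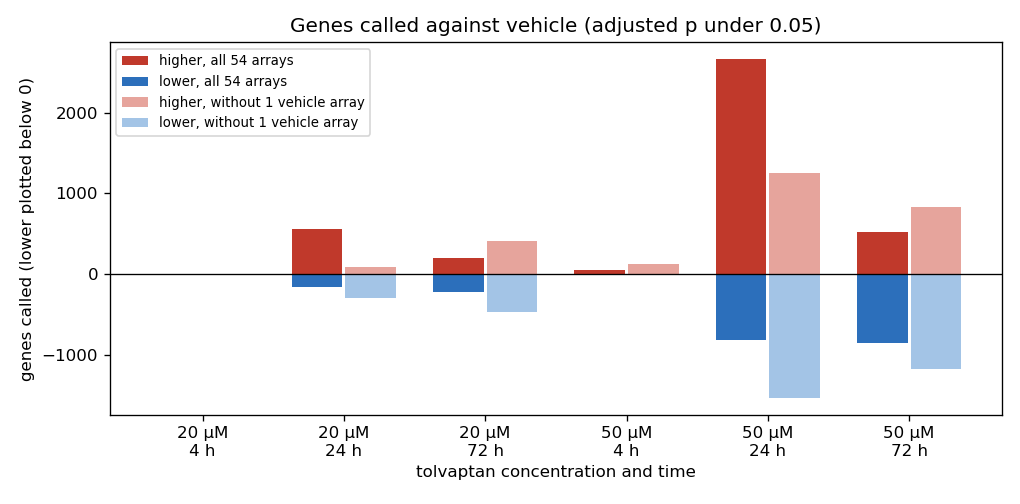
Genes called against vehicle by limma at each concentration (µM) and time (h), with higher calls above 0 and lower calls below 0; dark bars use all 54 arrays and light bars leave out the 24 h vehicle array of donor 1. At 50 µM and 24 h the numbers were 2660 and 816 with that array and 1256 and 1531 without it.

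At 72 h PXR and CAR targets were higher at 50 µM as well: 11 of 12 rose and none fell, with a median of 1.25 (11 adjusted over the list alone, adjusted p = 0.0167 with an estimated correlation). ALAS1 rose by 2.41 ± 0.20, CYP2C8 by 1.55 ± 0.20 and CYP2B6 by 1.54 ± 0.25. Of 15 NF-kB and cytokine genes 11 fell (12 adjusted over the list alone, median -0.71, adjusted p = 0.0156 with an estimated correlation), CCL20 by 2.53 ± 0.24, CXCL8 by 1.57 ± 0.19 and CX3CL1 by 1.13 ± 0.15. Of 20 cytoskeleton and SRF target genes 12 fell (14 adjusted over the list alone, median -0.38, adjusted p = 0.0185 with an estimated correlation), TUBA1A by 1.93 ± 0.26 and TPM1 by 0.73 ± 0.12. In the same samples 5 of 20 fibroblast markers fell, COL5A2 by 0.66 ± 0.14 and TIMP1 by 0.47 ± 0.14 (median -0.31, camera adjusted p = 0.00408, adjusted p = 0.29 with an estimated correlation). Of 10 cholangiocyte and progenitor markers 2 fell (median -0.23, camera adjusted p = 0.227).

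The bile acid synthesis gene AKR1D1 rose by 2.44 ± 0.19 at 72 h, PCK1 by 2.13 ± 0.54 (0.96 without donor 2, adjusted p = 0.284), NDRG1 by 1.83 ± 0.29, SLC13A5 by 1.77 ± 0.20, HMOX1 by 1.62 ± 0.28 and PDK4 by 1.53 ± 0.33. LECT2, which encodes a liver chemotactic factor, fell by 2.85 ± 0.16, PEG10 by 2.38 ± 0.24, ABCG1 by 2.18 ± 0.24, the alcohol dehydrogenase gene ADH1A by 2.04 ± 0.19 and TCEA2 by 2.00 ± 0.25. For TCEA2 the other of 2 probe sets had the opposite sign and was not called. Of 14 fatty acid synthesis genes 7 fell, SREBF1 by 1.19 ± 0.21, and of 14 YAP and TGF-beta targets 7 fell, INHBE by 1.71 ± 0.24. Of 10 FXR genes 5 fell, ABCB4 by 1.00 ± 0.20 (-0.47 without donor 3), and of 27 secreted proteins 12 fell, ITIH1 by 0.94 ± 0.11, where the list's median of -0.19 was 0.10 after centring on these same proteins. Adjusted over the list alone, 7, 8, 6 and 13 members fell. The FXR list was not called without the donor block (adjusted p = 0.142). These 4 lists did not pass with an estimated correlation (adjusted p = 0.483, 0.139, 0.115 and 0.17 in the order given).

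At 50 µM and 72 h 525 genes were called higher and 852 lower. Housekeeping centring turned these to 1337 and 580, centring on secreted proteins to 4217 and 278, and quantile normalization to 940 and 1002. Centring on secreted proteins moved the median of all genes from -0.005 to 0.291, and smaller falls turned to rises under it. The fit with no donor block called 146 genes, and when a donor was left out between 550 and 1393.

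**Figure D2:**
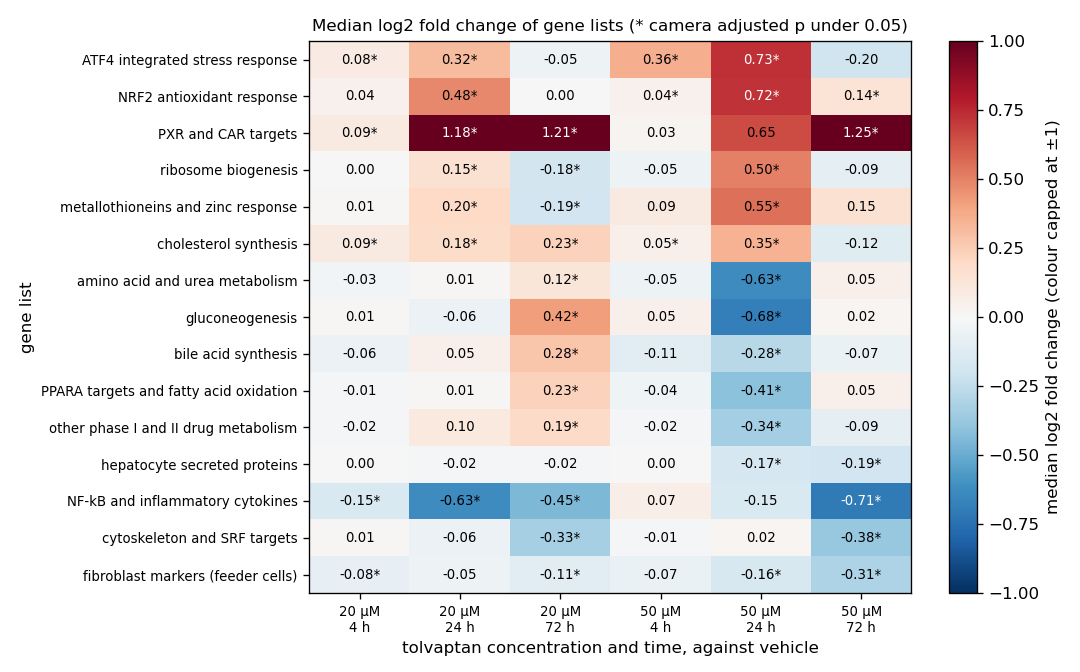
Median log2 fold change against vehicle of 15 gene lists (rows) at 20 and 50 µM and 3 times (columns); colour and number give the median, and an asterisk marks a camera adjusted p under 0.05 at the preset correlation. PXR and CAR targets had medians of 1.18, 1.21 and 1.25 at 20 µM and 24 h, 20 µM and 72 h, and 50 µM and 72 h.

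The 2 high concentrations were compared directly. At 24 h 1287 genes were higher and 713 lower at 50 than at 20 µM, but 909 and 981 without the 3 low arrays and 608 and 690 without donor 1. MAFF was higher by 3.13 ± 0.40, ERN1 by 2.01 ± 0.22 and HES4 by 1.96 ± 0.22, while PCK1 fell by 3.38 ± 0.54, CYP7A1 fell by 2.74 ± 0.44 and the amino acid transporter gene SLC38A4 fell by 2.11 ± 0.18. At 72 h 253 genes were higher and 504 lower, with OASL higher by 1.17 ± 0.31 (0.51 without donor 1), GDF15 by 1.14 ± 0.27 and USP2 by 1.13 ± 0.22, and MROH2A lower (-1.77 ± 0.35, and -1.05 without donor 3), TCEA2 lower (-1.71 ± 0.25) and SLC17A2 lower (-1.64 ± 0.23). At 4 h 13 genes were higher, led by IGFBP1 at 2.13 ± 0.42, C11orf96 at 1.59 ± 0.27 and DDIT3 at 1.53 ± 0.29, the last 2 at 0.93 and 1.01 without donor 3. The 4 h count was 0 without donor 2 and 0 without donor 3, so all these calls ended there, and 46 without donor 1. Leaving the donor block out gave counts of 1, 261 and 21 at 4, 24 and 72 h. At 72 h 559, 319 and 93 genes were called without donors 1, 2 and 3. After quantile normalization the splits were 1119 and 1111 at 24 h and 525 and 675 at 72 h. Centring on secreted proteins gave 4320 and 354 at 24 h and 3385 and 196 at 72 h, and housekeeping centring 382 and 474 at 72 h.

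The effect of 50 µM differed between times for many genes, by a test of the difference itself. Between 72 and 24 h 1962 genes differed, 428 with a higher and 1534 with a lower effect at 72 h. PCK1 fell by 3.53 at 24 h and was 2.13 higher than vehicle at 72 h (0.96 without donor 2), a difference of 5.66 ± 0.76 (adjusted p = 2.33e-06). PDK4 differed by 3.59 ± 0.46 and CYP7A1 by 3.17 ± 0.62, while CCL20 differed by -2.99 ± 0.34, MAFF by -2.90 ± 0.57 and CD109 by -2.88 ± 0.45. Between 24 and 4 h 1364 genes differed, 1057 with a higher effect at 24 h. Without the low vehicle array the splits were 885 and 908 for 72 against 24 h and 539 and 739 for 24 against 4 h. Housekeeping centring gave 833 and 825 and 595 and 542, centring on secreted proteins 657 and 669 and 1728 and 223, and quantile normalization 998 and 1082 and 834 and 803. With the donor block left out 172 and 32 genes were called. Without donors 1, 2 and 3 the counts were 1029, 1263 and 1156 for 72 against 24 h. For 24 against 4 h they were 788, 1072 and 378.

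Of the genes called at both 24 and 72 h at 50 µM, 205 rose at both times where independent lists would share 125, and 216 fell at both where 62.3 would be shared. A further 143 rose and then fell, against 203 for independent lists, and 46 fell and then rose, against 38.4. With the 24 h vehicle array of donor 1 left out the numbers were 199 against 93.1 and 424 against 161 for the same direction, and 99 against 132 and 99 against 114 for the opposite ones. Any concentration differed from vehicle, by a moderated F test, for 47 genes at 4 h, 2826 at 24 h and 1318 at 72 h.

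**Figure D3:**
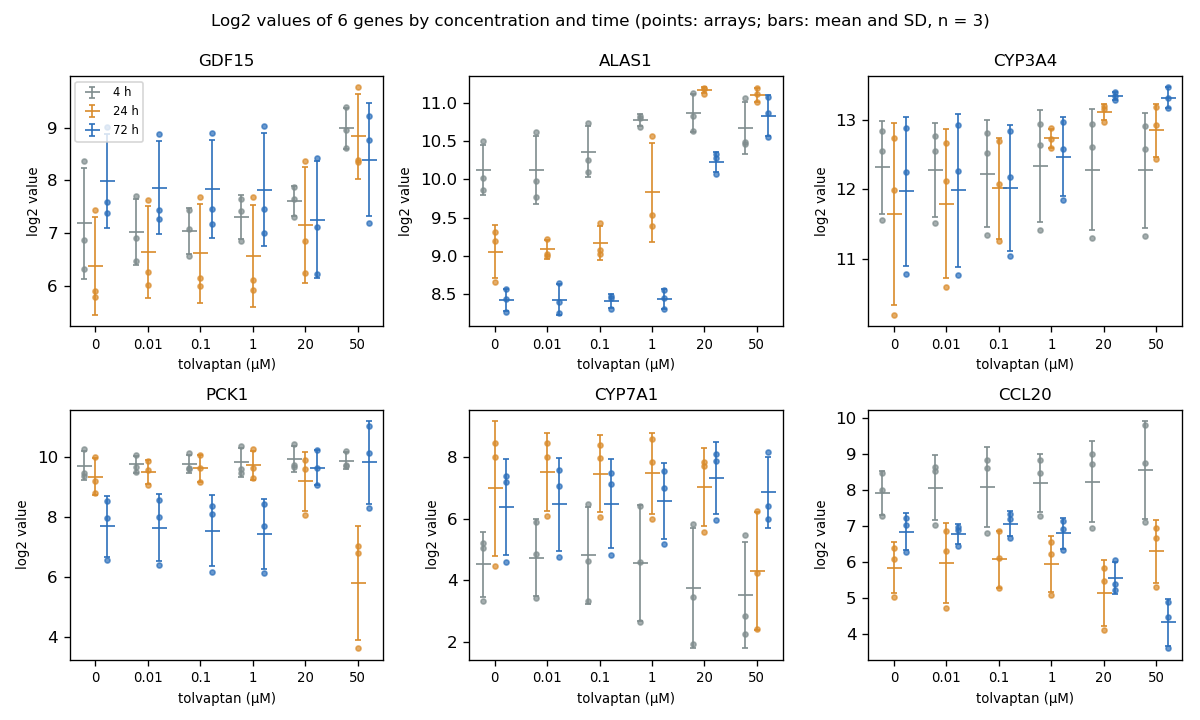
Log2 values of 6 genes (vertical axes) against tolvaptan concentration (µM, 0 is vehicle) at 4, 24 and 72 h; points are arrays, and bars give the mean and SD over 3 donors. At 24 h PCK1 was at 5.81 ± 1.90 (SD, n = 3) at 50 µM and 9.34 ± 0.61 (SD, n = 3) in vehicle.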

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

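The test of how many of the genes that rose and then fell keep both calls without the low vehicle array was set before its result was seen. The counts of splits and the other tests of this part were chosen after the results were seen, and the fit without that array was added after the array medians were seen.

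The difference between the effects of 50 µM at 24 and 4 h was called for 1364 genes, and that between 72 and 24 h for 1962 genes. The 6 effects of a donor at a time can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and the highest other split gave 718 genes for 24 against 4 h and 778 for 72 against 24 h. The real split gave the most in both, at 1 of 10. The single genes had these differences for 24 against 4 h: LINC01003 1.86 ± 0.31, CHML 1.82 ± 0.34, ERN1 1.80 ± 0.31, PCK1 -3.70 ± 0.76, SLC1A2 -2.65 ± 0.44 and IGF1 -2.37 ± 0.30. For 72 against 24 h they were PCK1 5.66 ± 0.76, PDK4 3.59 ± 0.46, CYP7A1 3.17 ± 0.62, CCL20 -2.99 ± 0.34, MAFF -2.90 ± 0.57 and CD109 -2.88 ± 0.45. Each of these 12 differences had an adjusted p under 0.05 without the low vehicle array too, from 1.48e-06 to 0.00441.

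Probe sets without a single gene symbol lay outside the comparisons by gene. Of 1230 of them, 383 were called at 50 µM and 24 h, 291 of them higher, and 128 at 72 h, 60 of them higher. These counts were not repeated without the low vehicle array, on which the balance over genes at 24 h depended.

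Rises outnumbered falls among the calls at 50 µM and 24 h, at 76.5 percent. Without the 24 h vehicle array of donor 1 rises were 45.1 percent, so the excess rests on that array. Among genes above the median level 75.6 percent of calls were rises, which argues against dim genes near the background. The median difference of all genes exceeded 0.1 in 1 of 3 donors and was -0.03 and -0.01 in the others, which argues against a shift present in every donor. What made that array low is open, and a biological cause in that culture was not tested.

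Of the genes called at both times at 50 µM, 46 fell at 24 h and rose at 72 h and 143 rose and then fell, which became 99 and 99 without the low vehicle array. The low vehicle array would have to lie about 1.68 above the same donor's arrays of 1 µM and below to carry the fall of the 46 genes. It lay at -0.39 (interquartile range 0.43), lower in 42 of 46. The array lay at -0.4 over all genes, with 86 percent lower, so this outcome was to be foreseen and is no separate test. Without the array 45 of the 46 genes kept both calls, so their falls do not rest on that array. As a low vehicle array lessens falls, this too was to be foreseen and is no separate test. A loss of hepatocyte RNA at 24 h that had recovered by 72 h would raise the secreted proteins along with the 46 genes. The change of the effect was 1.22 in the genes and -0.03 in the secreted proteins. That is a gap of 1.25 against interquartile ranges of 0.68 and 0.31, and the gap was 1.33 for the 9 secreted proteins with a mean level under 11. The 46 genes were chosen for a fall and then a rise. Their change and both gaps were thus largely fixed by that choice and decide nothing. The secreted proteins were not so chosen, and their median showed no rise (-0.03, and -0.11 in those 9). Of the 143 genes 52.4 percent kept both calls without that array, so for these the array and a change with time cannot be told apart, as part of the set depends on it. A response that reverses with time of exposure stays open for both sets, as untested.

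Cytoskeletal and SRF target genes fell at 72 h at 20 and 50 µM, with list medians of -0.33 and -0.38. Less RNA of the feeder fibroblasts could lower them, and the fibroblast markers had medians of -0.11 and -0.31 at 20 and 50 µM, lower than vehicle but less so than the list. This cannot be told apart from a change in the hepatocytes, because human probe sets chosen for the table may read mouse transcripts poorly.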

How the results depend on the processing

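Counts of calls depended on the block, on which arrays share the spread, and on 1 array. Of 284 counts under alternatives, 130 stayed within 1.5 times of the count reported and 154 did not. Settings with fewer arrays have fewer degrees of freedom, and the test of every probe set has more units. The cause of the other shifts was not tested. Arrays give no depth, and how far dim signals lie above background was not measured.

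Without the donor block, which pairs arrays of 1 donor, the counts were 1 for 50 µM at 4 h, 1190 for 50 µM at 24 h, 146 for 50 µM at 72 h, 33 for 20 µM at 24 h, 15 for 20 µM at 72 h and 1 for 50 against 20 µM at 4 h. They were 261 for 50 against 20 µM at 24 h, 21 for 50 against 20 µM at 72 h, 32 for the 50 µM effect at 24 against 4 h, 172 for the 50 µM effect at 72 against 24 h, 447 for vehicle at 24 against 4 h and 1046 for vehicle at 72 against 4 h in the same setting. They were 0 for 1 µM and below, 1 for any concentration at 4 h, 370 for any concentration at 24 h and 133 for any concentration at 72 h in the same setting. With 1 block per donor across times the counts were 8 for 50 µM at 4 h, 754 for 50 µM at 72 h, 227 for 20 µM at 24 h, 105 for 20 µM at 72 h, 2 for 50 against 20 µM at 4 h and 1103 for 50 against 20 µM at 24 h. They were 271 for 50 against 20 µM at 72 h, 487 for the 50 µM effect at 24 against 4 h, 1060 for the 50 µM effect at 72 against 24 h, 0 for 1 µM and below, 9 for any concentration at 4 h and 1524 for any concentration at 24 h in the same setting. They were 659 for any concentration at 72 h in the same setting. With only the arrays of the times compared the counts were 0 for 50 µM at 4 h, 1726 for 50 µM at 24 h, 58 for 20 µM at 24 h, 691 for 20 µM at 72 h, 1 for 50 against 20 µM at 4 h and 623 for 50 against 20 µM at 24 h. They were 1178 for 50 against 20 µM at 72 h, 866 for the 50 µM effect at 24 against 4 h, 0 for 1 µM and below, 0 for any concentration at 4 h and 647 for any concentration at 24 h in the same setting. With only the arrays of the groups compared the counts were 0 for 50 µM at 4 h, 44 for 50 µM at 24 h, 284 for 50 µM at 72 h, 4 for 20 µM at 24 h, 121 for 20 µM at 72 h and 0 for 50 against 20 µM at 4 h. They were 0 for 50 against 20 µM at 24 h, 4 for 50 against 20 µM at 72 h, 9 for the 50 µM effect at 24 against 4 h, 19 for the 50 µM effect at 72 against 24 h, 71 for vehicle at 24 against 4 h and 0 for 1 µM and below in the same setting. With every probe set tested alone the counts were 6018 for 50 µM at 24 h, 2156 for 50 µM at 72 h, 1365 for 20 µM at 24 h, 2088 for the 50 µM effect at 24 against 4 h, 3347 for the 50 µM effect at 72 against 24 h and 2325 for vehicle at 24 against 4 h. They were 3786 for vehicle at 72 against 4 h, 556 for 1 µM and below, 4769 for any concentration at 24 h and 2013 for any concentration at 72 h in the same setting. With the mean of a gene's probe sets the counts were 323 for 1 µM and below. With only genes above the median level the counts were 1478 for vehicle at 72 against 4 h and 454 for 1 µM and below. With housekeeping centring the counts were 119 for 50 µM at 4 h, 25 for 50 against 20 µM at 4 h, 1 for 1 µM and below and 71 for any concentration at 4 h. With centring on secreted proteins the counts were 84 for 50 µM at 4 h, 4495 for 50 µM at 72 h, 354 for 20 µM at 24 h, 20 for 50 against 20 µM at 4 h, 4674 for 50 against 20 µM at 24 h and 3581 for 50 against 20 µM at 72 h. They were 0 for 1 µM and below, 4950 for any concentration at 24 h and 5444 for any concentration at 72 h in the same setting. With quantile normalization repeated the counts were 117 for 50 µM at 4 h, 770 for 20 µM at 72 h, 29 for 50 against 20 µM at 4 h, 1200 for 50 against 20 µM at 72 h, 7 for 1 µM and below and 83 for any concentration at 4 h. With array weights the counts were 84 for 50 µM at 4 h, 2281 for 50 µM at 24 h, 121 for 20 µM at 24 h, 1657 for 20 µM at 72 h, 22 for 50 against 20 µM at 4 h and 3245 for 50 against 20 µM at 24 h. They were 1277 for the 50 µM effect at 72 against 24 h, 4107 for vehicle at 72 against 4 h, 7 for 1 µM and below, 78 for any concentration at 4 h and 2397 for any concentration at 72 h in the same setting. With a variance trend and robust prior the counts were 20 for 50 against 20 µM at 4 h and 208 for 1 µM and below. Minus the 3 low-median arrays at 24 h, chosen after seeing the data, the counts were 152 for 50 µM at 4 h, 2144 for 50 µM at 72 h, 145 for 20 µM at 24 h, 940 for 20 µM at 72 h, 32 for 50 against 20 µM at 4 h and 1339 for 50 against 20 µM at 72 h. They were 2475 for vehicle at 24 against 4 h, 109 for any concentration at 4 h and 2262 for any concentration at 72 h in the same setting.

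Leaving out each donor in turn, or the low vehicle array, gave counts of 0 to 246 for 50 µM at 4 h, 2283 to 3100 for 50 µM at 24 h, 550 to 1997 for 50 µM at 72 h, 0 to 5 for 20 µM at 4 h and 115 to 885 for 20 µM at 24 h. The range was 56 to 868 for 20 µM at 72 h, 0 to 46 for 50 against 20 µM at 4 h, 965 to 2718 for 50 against 20 µM at 24 h, 93 to 1276 for 50 against 20 µM at 72 h and 378 to 1278 for the 50 µM effect at 24 against 4 h. The range was 1029 to 1793 for the 50 µM effect at 72 against 24 h, 201 to 2278 for vehicle at 24 against 4 h, 743 to 3253 for vehicle at 72 against 4 h, 0 to 837 for 1 µM and below and 0 to 110 for any concentration at 4 h. The range was 1352 to 3013 for any concentration at 24 h and 440 to 2106 for any concentration at 72 h.

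Among 529 pairs of a named gene and a contrast, 8 changed sign in at least 1 setting and 46 kept sign and call in every setting that gave a value. With the mean of a gene's probe sets ACACA at 50 µM and 24 h was 0.02 and UGT1A6 at 50 µM and 72 h was -0.32. With centring on secreted proteins SDHA, SUCLG2 and PGK1 at 50 µM and 72 h were 0.03, 0.06 and 0.04. When a donor was left out, FOXA2, RPS15 and TPM4 at 50 µM and 24 h ran from -0.02 to 0.87, -0.02 to 0.51 and -0.10 to 1.25, the lowest each time without donor 1, and RPS15 was -0.01 without the low vehicle array and without the 3 low arrays. For lists, with only genes above the median level the medians at 20 µM and 4 h were 0.18 for hypoxia and 0.02 for NF-kB. The respiratory chain list at 20 µM and 24 h was -0.07 with quantile normalization repeated, -0.09 to 0.14 when a donor was left out and -0.09 without the 3 low arrays. The unfolded protein list at 20 µM and 4 h ran from -0.09 to 0.10. The cause was not tested. Of 288 list tests, 80 calls were lost with an estimated correlation. With fry 31 were lost and 16 gained. At 50 µM camera called 7 lists higher and 2 lower at 4 h, 8 and 13 at 24 h, and 4 and 14 at 72 h. Of these 1, 0 and 3 also passed with an estimated correlation. At 20 µM the calls were 3 and 3, 12 and 2, and 13 and 10, of which 0, 3 and 4 also passed. The list reversals above are by camera's direction against the other genes, and lists that passed in neither setting were not counted. The medians of further called lists changed sign while camera's direction did not, at 50 µM with centring on secreted proteins. At 24 h glycolysis went from -0.12 to 0.03 and the respiratory chain and TCA cycle each from -0.06 to 0.09. At 72 h transporters went from -0.28 to 0.02, secreted proteins from -0.19 to 0.10, glycolysis from -0.20 to 0.09, unfolded protein genes from -0.24 to 0.06, immediate early genes from -0.20 to 0.09, tRNA synthetases from -0.13 to 0.16 and histones from -0.29 to 0.01. Without the donor block 409 of the 529 named pairs and 32 list calls no longer passed and 1 list was gained, and the other list calls did not change. Not run were the fit on the groups compared for the test of any concentration, which equals the fit on its time, 1 block per donor for vehicle over time, which is the fit reported, and single genes with every probe set tested alone.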

Other observations

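The bounds of the hypothesis on culture time below were set before its result was seen, but the spread between donors was not part of them. The counts of splits were chosen after the results.

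Other groups moved at 50 µM. At 24 h 8 of 13 heat shock genes rose (median 0.36, camera adjusted p = 0.00572, adjusted p = 0.41 with an estimated correlation and 0.0593 without the donor block), HSPH1 by 1.03 ± 0.17 (0.59 without the low vehicle array) and HSPB8 by 0.88 ± 0.11, and 8 rose without that array too. Of 13 apoptosis regulators 7 rose (median 0.29, camera adjusted p = 0.0107, adjusted p = 0.404 with an estimated correlation), the death receptor gene TNFRSF10A by 1.16 ± 0.11 and BAX by 0.66 ± 0.14 (0.42 without that array, where 5 rose). Of 23 acute phase and complement genes 11 fell and 1 rose (adjusted p = 0.115 with an estimated correlation), C8A by 0.78 ± 0.15 and C3 by 0.65 ± 0.11, and 15 fell without that array.

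The vasopressin and cAMP list holds the signalling of the drug's target class. At 50 µM and 72 h 3 of its 12 genes rose, the water channel gene AQP3 by 0.98 ± 0.14, CREB3L3 by 1.07 ± 0.18 and PPARGC1A by 0.71 ± 0.21 (median 0.12, camera adjusted p = 0.0164, adjusted p = 0.397 with an estimated correlation and 0.0523 without the donor block). None of the 12 was called at 20 µM and 72 h (median 0.15, camera adjusted p = 0.0146, adjusted p = 0.395 with an estimated correlation and 0.0576 without the donor block).

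Of 4 measured Kupffer cell and leukocyte markers CD14 differed from vehicle by 1.27 at 50 µM and 1.20 at 20 µM at 72 h, while CD163 differed by -0.34 and -0.37 and CD74 by -0.42 and -0.18. The list was too short to test, as was that of endothelial markers, of which STAB1 was at 0.16 and LYVE1 at -0.20 at 50 µM and 72 h. The stellate cell list was called at neither concentration, with medians of 0.04 at 24 h and 0.01 at 72 h at 50 µM.

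Some values stand outside the rule for named genes and were chosen after they were seen. The probe set named for the immunoglobulin gene IGHA1 rose by 4.32 ± 0.51 at 20 µM and 24 h (adjusted p = 7.69e-07) and by the same 4.32 ± 0.51 at 50 µM and 72 h (adjusted p = 1.48e-07). It rose by 2.88 ± 0.51 at 50 µM and 24 h (adjusted p = 5.22e-05) and was at 1.62 ± 0.51 at 20 µM and 72 h (adjusted p = 0.0675). ZSCAN25 is named within the rule. Its brighter probe set rose by 1.74 ± 0.32 at 20 µM and 24 h, and its other probe set was at -0.28 ± 0.19 (adjusted p = 0.38). The gene adjoins the CYP3A genes in the reference table.

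A hypothesis was that 20 µM at 72 h may run against the changes of the cultures over time. Across 11154 genes, which are not independent, the change from 4 to 72 h in the arrays of 1 µM and below correlated with the 20 µM effect at -0.26, -0.1 and -0.06 in the 3 donors, with no array shared between the 2 sides. The value of -0.06 did not meet the bound of -0.1 set for every donor. The spread between donors leaves the hypothesis open, though weighing that spread was not part of the bounds written beforehand.

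Other splits of the arrays were counted for each number of calls. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split was the largest, at 1 of 10, for 50 µM against vehicle at 4 h (54 genes, at most 44 in another split), 24 h (3476 and 1847) and 72 h (1377 and 18), for 20 µM at 72 h (425 and 0), for 50 against 20 µM at 24 h (2000 and 196) and 72 h (757 and 65), and for vehicle at 72 against 4 h (2475 and 0). For 20 µM at 24 h 2 of 10 splits gave as many genes (721, with 835 in another), for 50 against 20 µM at 4 h 2 of 10 (13 and 18), and for vehicle at 24 against 4 h 2 of 10 (1351 and 2025). For 20 µM at 4 h, with 0 genes, all 10 did. Among splits that part every donor's pair, the largest other counts were 44, 1533 and 18 for 50 µM at 4, 24 and 72 h and 212 for 20 µM at 24 h. The largest other count among such splits was 0 for 50 against 20 µM at 4 h and 2025 for vehicle at 24 against 4 h. Splits that call more than the real one were seen at 4 and 24 h, and their cause was not tested.

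With concentration labels permuted within donors, 2 of 100 arrangements gave as many genes at 4 h (47, at most 55 in another), 2 of 100 at 24 h (2826 and 3110) and 1 of 100 at 72 h (1318 and 796). The real arrangement is counted in each, so permuted labels seldom gave as many genes. At 4 and 24 h another arrangement still called more than the real one, so chance is not excluded there. The 4 h count was 0 with only the 4 h arrays, and 0 without donor 2 or without donor 3. For 1 µM and below, 47 of 100 arrangements gave at least the 2 genes called, with up to 2346 in another, many times the real count. Large counts can thus arise without the real grouping, and their cause was not tested.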
